A study of Podospora anserina with 48 samples.

How the data were processed

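Total RNA of 48 samples was hybridised against a common reference, with the sample labelled Cy3 and the reference Cy5 on every array, per the labels. The samples are 4 strains of Podospora anserina (wild type S, ∆PaMpk1, ∆PaMpk2 and IDC343 PaNox1) in 3 colony zones with 4 biological replicates each, grown for 72 hours at 27 °C in light on M2 medium covered with cellophane, per the labels. The reference is a pool of wild-type cultures of both mating types, mycelium harvested after 48 and 96 hours and fertilised cultures harvested 48 and 96 hours after fertilisation, per the labels. No dyes were swapped, so a dye bias of a gene stays in its log2 ratio but cancels between groups.

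Each array was read with Agilent Feature Extraction 9.5.3.1, per the file headers. The deposited intensity columns used were the mean signal and the median local background of each spot in both channels, neither of them corrected, and the processed signals, from which the software had removed background and dye bias by a linear and a lowess step, per the file headers. The deposited log10 ratio of the scanner files is that of processed Cy5 over processed Cy3, per the file headers. The deposited value table of the series holds log2 ratios whose scale and direction no label states. Set against the scanner files, its values equal the processed log ratio with its sign turned, that is log2 of Cy3 over Cy5 with no centring of genes, within 0.001 for most spots. For 39 of the 48 columns the matching scanner file was the sample's own, and for 9 it was that of another replicate of the same group.

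Signals were background-corrected with normexp (offset 50, parameters fitted on all spots) in limma 3.58.1 under R 4.3.3, with version 1.17.8 of the package data.table, and normalized within each array by loess with the 1417 control spots at weight 0. Spots marked as outliers by the scanner software, 2.48% to 4.29% per array, were left out, and the 4 spots of each gene were averaged. The log2 ratio of Cy3 over Cy5 per gene and array was analysed. A gene was tested if it lay well above background in Cy3 on at least 3 of 4 arrays of at least 1 group, which held for 10041 of 10556 genes and left out 515. No gene was saturated on any array. Gene order came from a reference table of the assembly ASM22654v1, in which 10518 of the 10556 identifiers were found; since the files name no genome build, no coordinates are given.

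On 6 arrays, those with an interquartile range of log2 ratios under 0.4, this background correction fitted poorly. Between 5 and 84 of 43641 spots on them had a stray bright local background, and the background SD that normexp fitted was 364 to 1156. The other 42 arrays had 0 to 53 such spots and an SD of 0.624 to 258.6, with a median of 1.43. Log2 ratios on the 6 arrays had an interquartile range of 0.220 to 0.315 against 0.517 to 0.907 on the others. A second correction, chosen after the data were seen, fitted the parameters without spots whose local background exceeded 2 times the array's median and brought the background SD of the 6 arrays to 1.08 to 4.01. The planned correction was kept for the named genes and leading counts, and the second is given beside the total of each comparison. On a simulated array the slope on the true log2 ratio was 0.748 without bright spots, 0.229 with 10 of them, and 0.747 once they were left out of the parameter fit.

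All 48 arrays entered 1 linear model with a mean for each of the 12 groups and no covariates, fitted with lmFit and eBayes, and p-values were adjusted by Benjamini and Hochberg's method with a threshold of 0.05. Pairwise comparisons were the 3 zone steps of the wild type and each mutant against the wild type in each zone. F tests compared the zone changes of each mutant with those of the wild type and the mutants with each other over the 3 zones. Genes named per pairwise comparison are the 2 with the largest log2 difference upwards and the 2 downwards among genes past the threshold whose groups did not overlap, and for F tests the 2 with the largest F, a rule set before the data were examined for the case that no functional description is given. Lists by function were planned the same way, and none could be formed with the 3 tested genes needed. Tests on simulated data with 200 changed genes among 10041 recovered 51% of the genes changed 1.5-fold and 86% of those changed 2-fold for zone 1 against zone 2 of the wild type, 60% and 79% for ∆PaMpk1 in zone 1, 42% and 64% for the zone change of ∆PaMpk1, and 52% and 80% for ∆PaMpk1 against ∆PaMpk2. Of the genes called, 2.84%, 1.42%, 7.83% and 6.38% were false in these 4 tests, above the threshold of 5% for both F tests.

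Each of the 12 slides held 1 array of each strain, all of 1 zone, and each zone was scanned on 1 day. Slide could therefore be used as a block for comparisons of strains but not of zones. Median Cy5 signals were 1171 to 1372 on the day of zone 1, 952 to 1090 on that of zone 2 and 445 to 1136 on that of zone 3. Whether replicate numbers pair the samples was checked by the correlation of deviations from the group means. Same-numbered wild-type samples deviated together between zones 1 and 2 (0.103 to 0.521 over 4 pairs) and between zones 2 and 3 (0.199 to 0.428), so the numbers pair those samples. In no other pairwise comparison did every pair exceed 0.1 with the planned correction. Between neighbouring zones within each mutant, every pair with the same culture number in the titles exceeded 0.1 with the second background correction and not with the planned one, and the tests of zone steps within the mutants were run with and without this number as a random block.

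Gene lists were tested with camera (preset correlation 0.01, and an estimated correlation as the alternative), scores with exact permutation tests, and neighbouring genes with 100000 permutations of the changes over gene positions. Alternatives tried were no background subtraction, the processed signals, Aquantile, the Cy3 channel alone, the deposited table, no filter, a model of the compared groups alone, eBayes with trend and robust options, arrayWeights, replicate, culture and slide blocks, each array left out in turn, and exchanging or leaving out the 2 PaNox1 mutant arrays of conflicting titles. The brightest probe per gene was not run because each gene has 1 probe. The mitochondrial list, the zone score, the tests of neighbours, the scaling of log2 ratios between arrays, slide as a fixed block, leaving out each slide in turn, the culture block for zone steps within the mutants and leaving out 4 or 6 arrays were chosen after the data were seen.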

Results

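RNA from the filamentous fungus Podospora anserina was measured in 3 zones of the colony of 4 strains, on 48 2-colour arrays. The strains were the wild type S, ∆PaMpk1, which lacks a MAP kinase of the cell wall integrity type, ∆PaMpk2, which lacks a MAP kinase of the Fus3/Kss1 type, and IDC343 PaNox1, a mutant of an NADPH oxidase needed for fruiting bodies (the PaNox1 mutant). Zone 1 was the growing edge of the colony, zone 3 the part farthest from it and zone 2 lay between them, all harvested after 72 hours of growth in light. Each of the 12 combinations of strain and zone was measured on 4 arrays from 4 biological replicates, per the descriptions. The labels of 3 arrays conflict in part, and the descriptions were followed. The source name of wild-type zone 3 replicate 1 gives zone 2, although the array correlated best with wild-type zone 3 (0.919). The titles of PaNox1 mutant zone 1 replicate 3 and zone 3 replicate 4 carry numbers that point to each other's zone, although both arrays correlated best with the group of their description (0.89 and 0.94). The culture number in the title of ∆PaMpk1 zone 1 replicate 4 has no match in the other zones. A level is given as the log2 ratio of the sample (Cy3) to a common reference (Cy5) after normalization within the array, so that 0 is only roughly the level of the reference pool. A dye bias of a gene stays in its level, and genes dim in Cy3 can lie near 0. The mating-type genes FMR1, SMR1 and SMR2, well above background in Cy3 on 0 of 48 arrays, averaged -0.29, -0.08 and -0.17. On a simulated array without bright spots the slope on the true log2 ratio was 0.748, so true differences may be larger than those given. The arrays held 10556 genes with 4 spots each, of which 10041 were tested. Median Cy3 signals per array ran from 239 to 1116, and 82.9% to 96.8% of the genes lay well above background in Cy3. The number of arrays, 4 per group, limits the precision of every value. Of the 48 arrays, 44 correlated best with their own group and 4 with another zone of their own strain, zone 2 each time. Wild-type zone 1 replicate 1 did so with 0.88 against 0.872 for its own group, and wild-type zone 3 replicate 4 with 0.922 against 0.886. The others were ∆PaMpk2 zone 1 replicate 1 (0.97 against 0.946) and replicate 2 (0.962 against 0.961).

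The files name genes by locus identifiers and give no functional description, so genes are named by identifier, at most 2 higher and 2 lower per pairwise comparison. None of the gene lists planned by function had enough named members to be tested. PaMpk1, PaMpk2 and PaNox1 themselves could not be found among the identifiers, so the labels of the mutants were not checked on their target genes.

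Log2 ratios were compressed on 6 arrays, namely wild-type zone 3 replicates 2 and 3, ∆PaMpk2 zone 1 replicate 3 and zone 2 replicate 1, and PaNox1 mutant zone 1 replicate 3 and zone 3 replicate 3. Their slopes on the other arrays of their groups were 0.511 to 0.660, against 0.767 to 1.14 on the other 42 arrays. When spots of bright local background were left out of the fit of the background parameters, the slopes of the 6 arrays were 0.948 to 1.03. Smaller rises were seen on some of the other 42 arrays. Slopes rose from 0.767 to 0.954 on wild-type zone 1 replicate 4 and from 0.778 to 0.936 on ∆PaMpk1 zone 3 replicate 3. They rose from 0.878 to 1.03 on ∆PaMpk1 zone 2 replicate 1 and from 0.907 to 1.01 on PaNox1 mutant zone 2 replicate 1. This second background correction was chosen after the data were seen. Its counts are given beside the total of each comparison, and beside other counts where stated. In all 12 pairwise comparisons no gene called under both changed direction. With it, 43 of the 48 genes named for pairwise comparisons and 4 of the 12 named for F tests were still those the naming rule picked, and the others still passed.

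**Figure D1:**
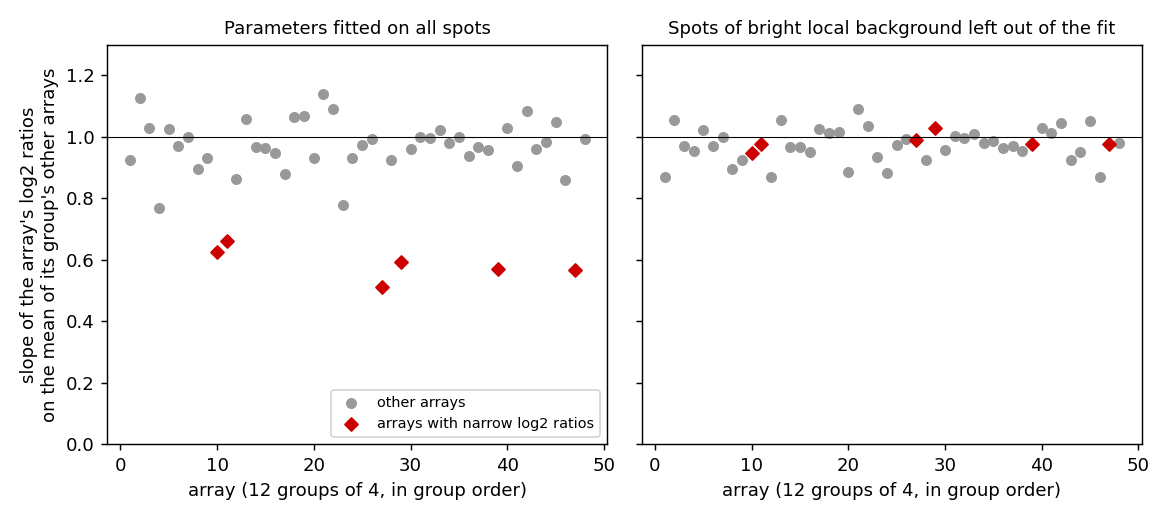
Slope of each array's log2 ratios on the mean of the other arrays of its group that were not compressed (vertical axis, no unit) for the 48 arrays (horizontal axis, in group order), with background parameters fitted on all spots (left) or without spots of bright local background (right). The 6 compressed arrays (diamonds) lie at 0.511 to 0.660 on the left and at 0.948 to 1.03 on the right.

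The wild-type zones show how expression differs between the growing edge and older parts of the colony. Pa_2_2310 was 12.3-fold higher in zone 2 (log2 ratio 0.95 ± 0.16, SD, n = 4) than in zone 1 (-2.67 ± 0.95, n = 4; limma adjusted p = 7.23e-06). Pa_1_110 was 10.7-fold higher in zone 2 (3.14 ± 0.56 against -0.28 ± 0.84, SD, n = 4 each; limma adjusted p = 0.000241). Pa_4_5490 was 32.9-fold lower in zone 2 (-3.90 ± 0.12 against 1.14 ± 0.72, SD, n = 4 each; limma adjusted p = 8.46e-10), and Pa_3_10370 was 9.58-fold lower (-0.73 ± 0.38 against 2.53 ± 0.35). Of the 10041 genes, 3268 differed between zones 1 and 2, with 1829 higher and 1439 lower in zone 2, among them 529 at least 2-fold higher and 156 at least 2-fold lower. The second background correction gave 4251 genes, which included 99.8% of the 3268.

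From zone 2 to zone 3 fewer genes differed. Pa_3_3210 was 6.55-fold higher in zone 3 (2.68 ± 0.53 against -0.03 ± 0.78, SD, n = 4 each; limma adjusted p = 0.00296) and Pa_5_4670 3.91-fold higher (1.29 ± 0.76 against -0.68 ± 0.55). Pa_3_2920 was 7.94-fold lower in zone 3 (-0.45 ± 0.19 against 2.54 ± 0.55, SD, n = 4 each; limma adjusted p = 0.00106) and Pa_5_1850 7.70-fold lower (-0.46 ± 0.63 against 2.48 ± 0.26). In all, 419 genes were higher and 220 lower, 639 of 10041 genes, with 86 and 36 of them at least 2-fold. With the second background correction 1445 genes passed, 142 and 34 of them at least 2-fold higher and lower. The count was 111 without the 6 compressed arrays and 179 without replicate 3 of zone 3 alone.

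Between the growing edge and zone 3, Pa_2_2310 differed most upwards, 29.6-fold (2.22 ± 0.49 against -2.67 ± 0.95, SD, n = 4 each; limma adjusted p = 1.03e-08), followed by Pa_3_3210, 27.8-fold (2.68 ± 0.53 against -2.12 ± 1.03). Pa_4_5490 was 16.5-fold lower in zone 3 (-2.90 ± 0.94 against 1.14 ± 0.72, SD, n = 4 each; limma adjusted p = 1.7e-08) and Pa_5_1850 13.4-fold lower (-0.46 ± 0.63 against 3.28 ± 0.35). In zone 3, 2468 genes were higher and 1728 lower than in zone 1, 4196 in all, and 903 were at least 2-fold higher against 190 at least 2-fold lower. The second background correction gave 5602 genes, which included 99.2% of the 4196. The balance of higher and lower genes depended on the scaling, since the scanner software's processed signals gave 1945 higher and 2509 lower for zone 2 against zone 1, 808 and 773 for zone 3 against zone 2, and 2527 and 3496 for zone 3 against zone 1. Each zone was hybridised on its own 4 slides and scanned on its own day, so zone and scan day cannot be told apart in these comparisons.

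**Figure D2:**
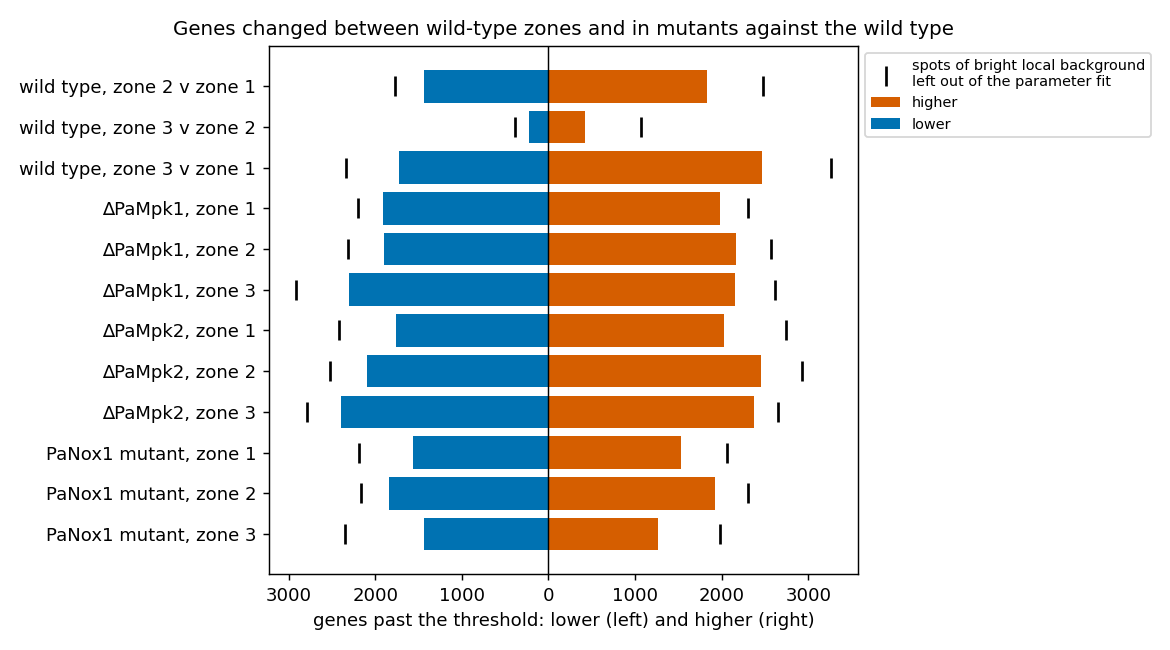
Number of genes higher (right, orange) and lower (left, blue) past an adjusted p of 0.05, for the 3 comparisons of wild-type zones and for each mutant against the wild type in each zone, with black marks for the counts under the second background correction. With the planned correction, zone 3 against zone 2 of the wild type has the fewest genes, 639, and ∆PaMpk2 in zone 3 the most, 4766; with the second, zone 3 against zone 2 has the fewest, 1445, and zone 3 against zone 1 of the wild type the most, 5602.

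The comparison of ∆PaMpk1 with the wild type shows which genes differ without this kinase. At the growing edge, Pa_1_7520 was 16.5-fold higher in ∆PaMpk1 (3.87 ± 0.12 against -0.18 ± 0.67, SD, n = 4 each; limma adjusted p = 1.61e-10) and Pa_2_6720 16.2-fold higher (3.65 ± 0.35 against -0.36 ± 0.18). Pa_1_3450 was lower by -5.32 on the log2 scale (-4.07 ± 0.61 against 1.25 ± 0.46, SD, n = 4 each; limma adjusted p = 2.26e-15) and Pa_5_6620 23.9-fold lower (-3.92 ± 0.31 against 0.65 ± 0.41). In zone 2, Pa_5_7880 was 19.1-fold higher (1.37 ± 0.17 against -2.89 ± 0.20), Pa_1_30 13.9-fold higher (3.52 ± 0.28 against -0.28 ± 0.35) and Pa_1_21970 54.3-fold lower (log2 difference -5.76, SE 0.47, n = 4 each; limma adjusted p = 1.44e-12). Pa_6_10630 was also lower in zone 2 (limma adjusted p = 2.11e-10), with no fold given because in ∆PaMpk1 it lay well above background on 1 of 4 arrays. In zone 3, Pa_1_23550 was 17.2-fold higher (3.42 ± 0.27 against -0.68 ± 0.59), Pa_7_4770 15.9-fold higher (3.41 ± 0.08 against -0.58 ± 0.30), Pa_3_3210 40.9-fold lower (-2.68 ± 0.48 against 2.68 ± 0.53) and Pa_2_7580 40.7-fold lower (-3.86 ± 0.36 against 1.49 ± 0.48, SD, n = 4 each; limma adjusted p = 7.42e-19).

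In ∆PaMpk1, 1975 genes were higher and 1915 lower in zone 1 (3890 of 10041), 2167 and 1897 in zone 2 (4064), and 2156 and 2307 in zone 3 (4463). Among genes changed at least 2-fold, lower ones outnumbered higher ones in each zone, with 623 against 371, 713 against 409 and 813 against 437. The same direction in all 3 zones was found for 2034 genes, 945 higher and 1089 lower, and for 2574, 1242 higher and 1332 lower, with the second background correction. With that correction the counts in zones 1, 2 and 3 were 4498, 4882 and 5534. With slide as a block, the counts were 3937, 4067 and 4495. When each slide was left out of the fit in turn, 81.1% to 97.7%, 82.8% to 99.1% and 89.0% to 98.5% of the genes called on the other slides had the direction of the call on that slide, where chance gives 50%.

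∆PaMpk2 was compared with the wild type in the same way. Pa_1_6440 was higher in all 3 zones, 48.4-fold in zone 1 (3.66 ± 0.24 against -1.93 ± 0.42, SD, n = 4 each; limma adjusted p = 3.51e-18), 47.7-fold in zone 2 (4.07 ± 0.07 against -1.51 ± 0.34) and 20.3-fold in zone 3 (3.91 ± 0.17 against -0.44 ± 1.11). Pa_0_800 was 24.1-fold higher in zone 1 (3.83 ± 0.35 against -0.76 ± 0.63), Pa_6_10170 22.3-fold higher in zone 2 (3.74 ± 0.17 against -0.74 ± 0.46) and Pa_4_6020 25.5-fold higher in zone 3 (4.63 ± 0.22 against -0.04 ± 0.43). At the growing edge Pa_3_2920 was 18.3-fold lower (-2.10 ± 0.68 against 2.09 ± 0.93, SD, n = 4 each; limma adjusted p = 1.4e-07) and Pa_2_11900 15.5-fold lower (-4.69 ± 0.82 against -0.73 ± 0.85). In zone 2, Pa_6_7580 was 26.8-fold lower (-4.26 ± 0.66 against 0.48 ± 0.53) and Pa_3_8110 25.7-fold lower (-2.78 ± 1.11 against 1.90 ± 0.56). In zone 3, Pa_3_3210 was 64.2-fold lower (-3.33 ± 0.41 against 2.68 ± 0.53, SD, n = 4 each; limma adjusted p = 4.24e-11) and Pa_1_9180 49.3-fold lower (-3.80 ± 0.20 against 1.83 ± 0.43).

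In ∆PaMpk2, 2024 genes were higher and 1759 lower in zone 1 (3783 of 10041), 2449 and 2099 in zone 2 (4548), and 2373 and 2393 in zone 3 (4766). At least 2-fold changes numbered 460 higher and 463 lower in zone 1, 523 and 764 in zone 2, and 605 and 942 in zone 3. Across the 3 zones 1999 genes kept 1 direction, 1122 higher and 877 lower, and 2862, 1509 higher and 1353 lower, with the second background correction. Under the second background correction 5166, 5440 and 5445 genes passed. The slide block gave 3835, 4596 and 4804, and on the slide left out 83.0% to 97.4%, 85.3% to 99.7% and 89.6% to 97.6% of the genes called on the others had the direction of the call.

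The PaNox1 mutant was compared with the wild type zone by zone. Pa_7_4760 was 19.1-fold higher in zone 1 (2.05 ± 0.31 against -2.21 ± 0.30, SD, n = 4 each; limma adjusted p = 2.76e-12) and 23.3-fold higher in zone 2 (1.00 ± 0.05 against -3.54 ± 0.18). Pa_2_7870 was 12.1-fold higher in zone 1 (1.94 ± 0.14 against -1.65 ± 0.58) and Pa_1_7120 28.4-fold higher in zone 2 (2.35 ± 0.45 against -2.48 ± 0.21). Pa_1_9180 was 38.4-fold lower in zone 2 (-4.21 ± 0.22 against 1.05 ± 0.08, SD, n = 4 each; limma adjusted p = 2.94e-17) and 41.8-fold lower in zone 3 (-3.56 ± 0.30 against 1.83 ± 0.43). Pa_4_4220 was 30.3-fold lower in zone 1 (-3.13 ± 0.80 against 1.79 ± 0.70), Pa_6_9560 30.3-fold lower in zone 2 (-2.71 ± 0.32 against 2.21 ± 0.48) and Pa_1_20870 25.9-fold lower in zone 3 (-3.62 ± 0.44 against 1.08 ± 0.52). Pa_3_2920 was 30.4-fold lower in zone 1 (-2.83 ± 0.53 against 2.09 ± 0.93) and 7.99-fold higher in zone 3 (2.55 ± 0.10 against -0.45 ± 0.19, SD, n = 4 each; limma adjusted p = 6.29e-05), where Pa_5_11050 was 7.84-fold higher (3.63 ± 0.42 against 0.66 ± 0.75). With the 2 PaNox1 mutant arrays of conflicting titles left out, the log2 difference of Pa_3_2920 in zone 3 was 3.02 (limma adjusted p = 0.000299), and with their zones exchanged it was 1.77 (limma adjusted p = 0.205).

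In the PaNox1 mutant, 1533 genes were higher and 1561 lower in zone 1 (3094 of 10041), 1924 and 1845 in zone 2 (3769), and 1265 and 1434 in zone 3 (2699). Of these, 276 were at least 2-fold higher and 515 at least 2-fold lower in zone 1, 385 and 702 in zone 2, and 279 and 517 in zone 3. The same direction in all 3 zones was found for 919 genes, 383 higher and 536 lower, and for 1574, 654 higher and 920 lower, with the second background correction. With that correction 4258 and 4468 genes passed in zones 1 and 2 and, in zone 3, 4329, over 1.5 times the planned count. With slide as a block the counts were 3128, 3779 and 2750, and on the slide left out 77.1% to 99.7%, 80.5% to 99.4% and 65.2% to 99.1% of the genes called on the others had the direction of the call (90.4% to 97.8% in zone 3 with the second background correction).

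Genes whose change across the zones differed between a mutant and the wild type were tested with an F test over both zone steps. Pa_7_5760 went from -0.94 ± 0.29 in zone 1 of the wild type to 0.54 ± 0.25 in zone 3, and from -0.73 ± 0.25 to -1.27 ± 0.13 in ∆PaMpk1 (SD, n = 4 each; F = 72.3, limma adjusted p = 5.46e-10) and -0.67 ± 0.15 to -1.13 ± 0.22 in ∆PaMpk2 (F = 63.3). Pa_6_11300 went from 0.80 ± 0.23 to -0.48 ± 0.29 in the wild type, from 0.12 ± 0.12 to 0.88 ± 0.20 in ∆PaMpk1 (F = 71.5) and from 0.30 ± 0.13 to 0.98 ± 0.14 in the PaNox1 mutant (F = 65.7). Pa_7_2290 went from 0.60 ± 0.07 to -1.29 ± 0.14 in the wild type and from -0.78 ± 0.34 to -0.95 ± 0.24 in ∆PaMpk2 (F = 51.9). Pa_3_2920 went from 2.09 ± 0.93 to -0.45 ± 0.19 in the wild type and from -2.83 ± 0.53 to 2.55 ± 0.10 in the PaNox1 mutant (F = 53.6). In ∆PaMpk1 1146 of 10041 genes passed, in ∆PaMpk2 1793 and in the PaNox1 mutant 1869. The change from zone 1 to zone 3 was smaller than in the wild type for 58.7% of these genes in ∆PaMpk1, 61.5% in ∆PaMpk2 and 36.3% in the PaNox1 mutant, against 54.2%, 57.4% and 47.0% of all genes tested. It had the opposite sign to the wild type for 692 of the 1146, 1007 of the 1793 and 757 of the 1869 genes. The F test picks genes whose zone changes differ, which favours opposite signs, and the share over all genes was not computed. The second background correction gave 2356, 2879 and 3312 genes, over 1.5 times as many in each strain. Of these, 68.1%, 71.1% and 42.8% changed less than in the wild type, against 58.2%, 60.1% and 47.0% of all genes tested under that correction. The opposite sign was found for 1257, 1427 and 1225. With it the 2 genes of largest F for the PaNox1 mutant were Pa_1_1045 (F = 229.6) and Pa_1_21710 (F = 187.5), in place of Pa_6_11300 and Pa_3_2920. For the PaNox1 mutant, leaving out the 2 arrays of conflicting titles gave 1991 genes and exchanging their zones 786. With slide as a block the counts were 1186, 1925 and 1963, and no test within 1 slide was possible because each slide held 1 zone.

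The mutants were also compared with each other over the 3 zones. Pa_6_11025 stood at 3.38 ± 0.06 in zone 1 of ∆PaMpk2, 2.23 ± 0.08 in the PaNox1 mutant and -1.71 ± 0.27 in ∆PaMpk1, with -0.91 ± 0.10 in the wild type (SD, n = 4 each; F = 976 for ∆PaMpk1 against ∆PaMpk2, limma adjusted p = 2.45e-32). Pa_6_10900 stood at -2.16 ± 0.10 in zone 1 of ∆PaMpk1, 0.26 ± 0.03 in ∆PaMpk2 and -0.47 ± 0.20 in the PaNox1 mutant, with -0.04 ± 0.12 in the wild type. Pa_0_800 stood at 3.83 ± 0.35 in zone 1 of ∆PaMpk2 and -0.63 ± 0.39 in the PaNox1 mutant (F = 313, limma adjusted p = 4.66e-23), and Pa_3_9590 at -0.53 ± 0.36 and 2.25 ± 0.26 (F = 249). The number of genes that differed was 5542 between ∆PaMpk1 and ∆PaMpk2, 4710 between ∆PaMpk1 and the PaNox1 mutant and 5260 between ∆PaMpk2 and the PaNox1 mutant. With the second background correction Pa_3_11348 had the largest F for the PaNox1 mutant against ∆PaMpk1 (F = 985.9) and against ∆PaMpk2 (F = 853.5). Counts under that correction were 6553, 5894 and 6679, and with slide as a block under the planned one 5575, 4718 and 5263. The fit took arrays of the same culture in different zones as independent. For these comparisons no culture block was run under the second correction, so its counts may be too high.

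**Figure D3:**
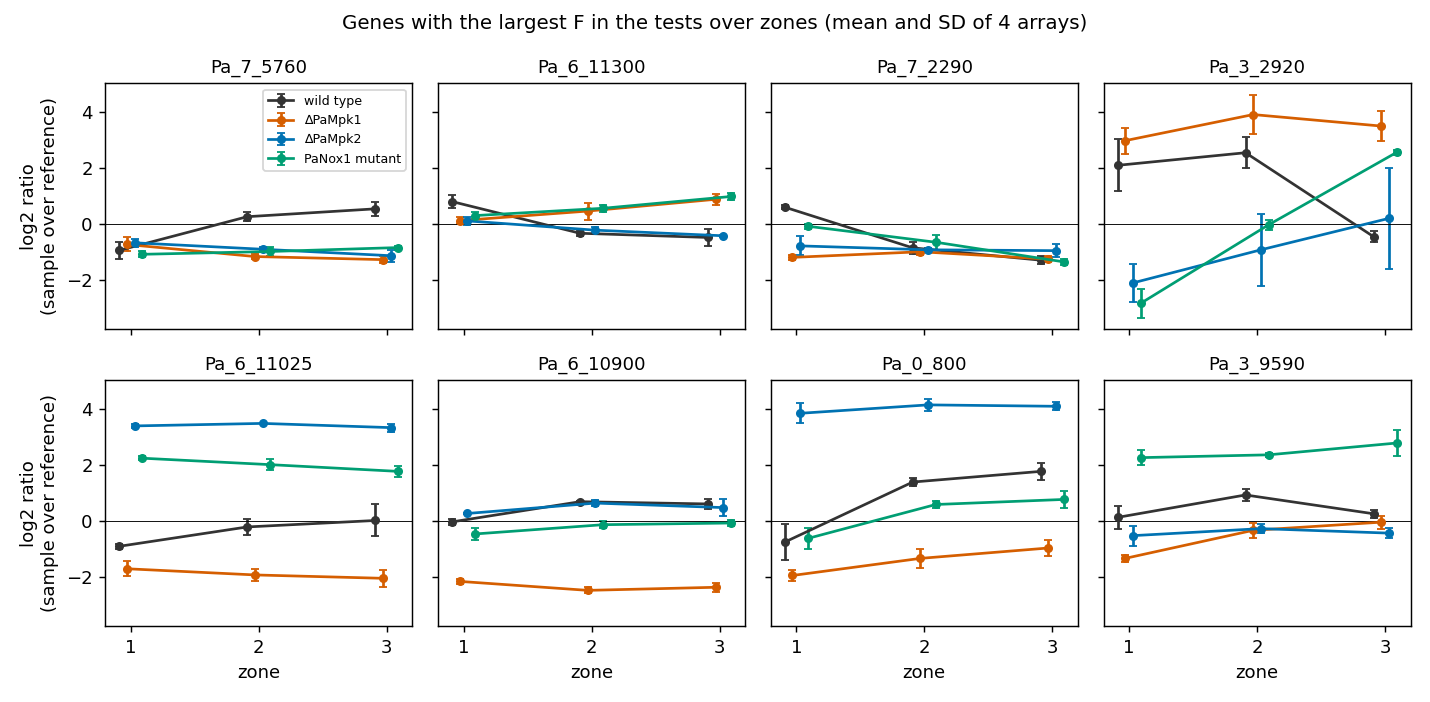
Log2 ratio of sample over reference (vertical axis) in zones 1 to 3 (horizontal axis) for 8 genes named by the F tests over zones, as mean and SD of 4 arrays per strain and zone. Pa_6_11025 lies at 3.38 in zone 1 of ∆PaMpk2 and at -1.71 in zone 1 of ∆PaMpk1, and Pa_3_2920 runs from -2.83 in zone 1 to 2.55 in zone 3 of the PaNox1 mutant.

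Genes changed in 1 mutant were often changed the same way in another. In zone 2, ∆PaMpk2 and the PaNox1 mutant shared 1223 higher and 1298 lower genes, where independent lists of these sizes would share 469 and 386, and 117 genes went opposite ways. In zone 3, ∆PaMpk1 and ∆PaMpk2 shared 1038 higher and 1389 lower genes, with 510 and 550 for independent lists. With the second background correction these counts were 1496 and 1579 with 192 opposite, and 1354 and 1831. All 3 mutants had 519 higher and 597 lower genes in common in zone 1, 702 and 817 in zone 2, and 469 and 858 in zone 3, which became 728 and 864, 883 and 1049, and 769 and 1387 with the second background correction. Mutants share their wild-type arrays, which in 100 simulated sets without any effect gave a mean covariance of log2 changes of 0.0228 (highest 0.0778). The observed covariance across genes ran from 0.222 (∆PaMpk1 and the PaNox1 mutant in zone 1) to 0.411 (∆PaMpk2 and the PaNox1 mutant in zone 2). When each mutant was set against its own 2 of the 4 wild-type arrays, ∆PaMpk2 and the PaNox1 mutant shared 1609 to 1757 genes of 1 direction in zone 2.

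How far each array had moved along the wild-type zone change was expressed as a score, defined after the data were seen. The score is the median log2 ratio of rising genes minus that of falling genes. Rising genes were at least 2-fold higher in zone 3 than in zone 1 of the wild type, falling genes at least 2-fold lower. For both, the arrays of the zones compared could not overlap. Each wild-type array was scored with genes chosen without its replicate number. A mutant array was given the mean score over the 4 choices that leave out 1 replicate number each. Wild-type scores were -1.55 ± 0.57 in zone 1, 0.52 ± 0.50 in zone 2 and 1.10 ± 0.24 in zone 3 (SD, n = 4 each). In zone 1 no difference from the wild type passed the test, with values of -0.08 (exact permutation p = 0.971), 0.04 (p = 0.771) and -0.35 (p = 0.457) for ∆PaMpk1, ∆PaMpk2 and the PaNox1 mutant. In zone 2 the mutants lay lower by -1.15, -1.43 and -1.65, and in zone 3 by -1.02, -1.28 and -0.85, in the same order, with all 4 mutant arrays below all 4 wild-type arrays each time. The 2-sided exact permutation p was 0.0286 in each of these 6 comparisons, the smallest that 4 against 4 arrays allow (0.0371 adjusted over 13 tests). The same 6 differences passed with the second background correction. In zone 1 that correction gave 0.08, -0.17 and -0.48 in the same order (exact permutation p = 0.857, 0.8 and 0.0857), none of which passed. The score genes were chosen on the wild type alone, so a lower score in another strain is expected in part from that choice. How large that part is was not tested. Every strain still moved upwards from zone 1 to zone 3, by 2.65 in the wild type, 1.71 in ∆PaMpk1, 1.33 in ∆PaMpk2 and 2.15 in the PaNox1 mutant. The second background correction gave 2.92, 1.58, 1.59 and 2.37 in the same order.

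**Figure D4:**
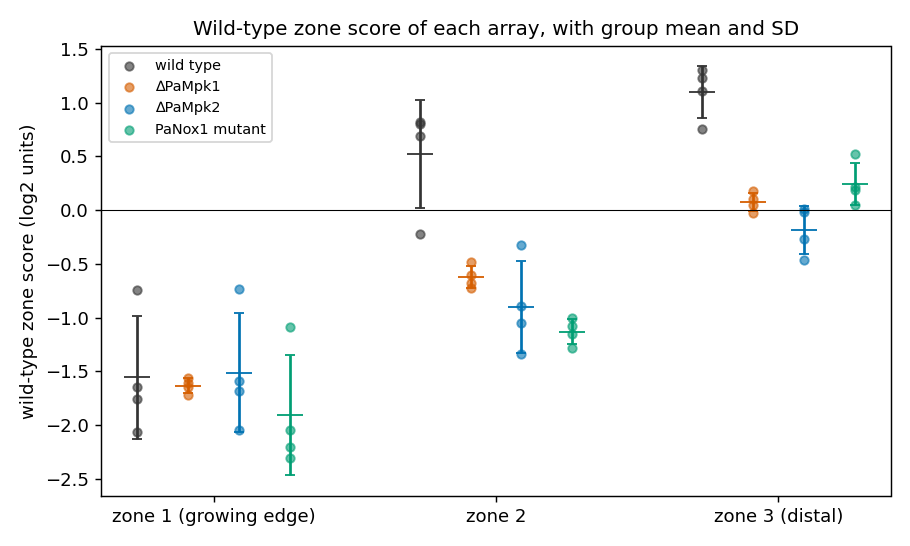
Wild-type zone score (vertical axis, log2 units) of each of the 48 arrays by zone (horizontal axis) and strain (colour), with group mean and SD. In zones 2 and 3 all 4 arrays of each mutant lie below the 4 wild-type arrays, which average 0.52 and 1.10.

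Neighbouring genes changed together more often than permuted gene positions gave, a test chosen after the data were seen that takes gene order from the assembly ASM22654v1. Of the genes changed at least 2-fold in zone 2 of ∆PaMpk2, 147 adjacent pairs went the same way, against a mean of 87.3 under 100000 permutations (p = 1e-05, the smallest they can give, adjusted p = 1.2e-05). The number of pairs exceeded the permuted mean in all 12 pairwise comparisons, with adjusted p of 1.2e-05 to 0.00165. The following runs were chosen after their values were seen. The 6 neighbours from Pa_2_7870 to Pa_2_7920 were higher in every mutant and zone, with median log2 changes of 2.15, 1.57 and 1.65 in zones 1, 2 and 3 of ∆PaMpk1, 3.03, 2.24 and 2.52 in ∆PaMpk2, and 2.71, 1.73 and 1.32 in the PaNox1 mutant, and all 6 genes passed each time. The 5 genes from Pa_6_7840 to Pa_6_7880 were lower in ∆PaMpk2, with medians of -2.58, -2.66 and -3.93, and all 5 passed in each zone. In ∆PaMpk1 their medians were -1.35, -1.29 and -1.08, with 3 of the 5 lower in each zone, and in the PaNox1 mutant -0.74, -0.64 and -1.67, with 3, 2 and 5 lower. The 3 genes from Pa_4_4230 to Pa_4_4210 were lower in the PaNox1 mutant, with medians of -4.76, -3.11 and -2.20, and all 3 passed in each zone. In ∆PaMpk2 their medians were -2.15, -1.66 and -0.80, with 3, 3 and 1 of the 3 lower, and in ∆PaMpk1 0 of the 3 passed in any zone. The 4 genes from Pa_2_14020 to Pa_2_14030 were lower in ∆PaMpk1, with medians of -2.62, -2.15 and -1.95, and all 4 passed in each zone. Of these 4, in zones 1, 2 and 3, 2, 1 and 3 were lower and 1, 1 and 0 higher in ∆PaMpk2, and 2 were lower in each zone of the PaNox1 mutant. In the mutants the medians of the 4 runs kept their sign under all 7 scalings tried, but some moved by over 1.5 times. For the genes from Pa_4_4230 to Pa_4_4210 in zone 3 they ran from -3.95 to -2.20 in the PaNox1 mutant, -2.26 to -0.73 in ∆PaMpk2 and -2.19 to -0.24 in ∆PaMpk1, and in zone 2 of ∆PaMpk2 from -1.77 to -0.66. For those from Pa_2_14020 to Pa_2_14030 in zone 3 of ∆PaMpk1 they ran from -2.94 to -1.95.

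**Figure D5:**
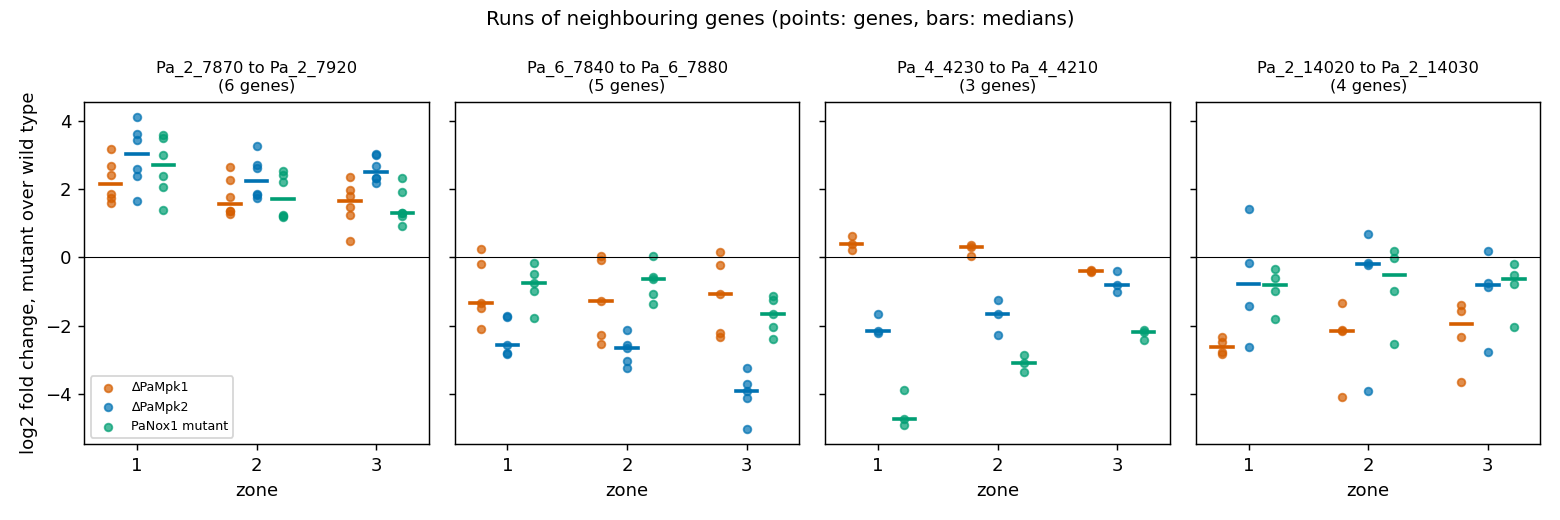
Log2 fold change of mutant over wild type (vertical axis) by zone (horizontal axis) and mutant (colour) for 4 runs of neighbouring genes, with a point per gene and a bar at the median. The genes from Pa_2_7870 to Pa_2_7920 lie above 0 in all 3 mutants, and those from Pa_6_7840 to Pa_6_7880 have medians of -2.58, -2.66 and -3.93 in ∆PaMpk2.

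Genes of the mitochondrial genome carry their usual names in the files, and 15 of 17 were tested as a list chosen after these names were seen. Most encode subunits of the respiratory chain and of ATP synthase. In the wild type, 10 of the 15 were lower in zone 2 than in zone 1, 5 did not pass and 0 were higher, with a median log2 change of -0.70. Examples were nad4 (2.55-fold lower, limma adjusted p = 4.75e-06), cox2 (2.50-fold lower) and cox1 (1.94-fold lower). The mean of the list was -1.28 ± 0.13 in zone 2 and -0.54 ± 0.13 in zone 1 (SD, n = 4 each), and camera with a preset correlation gave an adjusted p of 1.91e-05, which was lost with an estimated correlation (adjusted p = 0.379). In zone 3 of ∆PaMpk2, 12 of the 15 were lower than in the wild type and 3 did not pass, with a median of -1.14 (camera adjusted p = 0.000127; adjusted p = 0.999 with an estimated correlation). There, cox3 was 2.96-fold lower, nad5 2.62-fold lower, and rps3, a ribosomal protein gene, 2.39-fold lower (limma adjusted p = 6.95e-07). The list mean in zone 3 was -2.00 ± 0.13 in ∆PaMpk2 and -0.95 ± 0.48 in the wild type (SD, n = 4 each). The compressed wild-type replicates 2 and 3 lay at -0.71 and -0.40, the others at -1.24 and -1.45, and all mutants share these wild-type arrays. With the second background correction replicates 2 and 3 lay at -0.94 and -0.49, still above the others at -1.24 and -1.45. In zone 3 of ∆PaMpk2, 12 of the 15 were lower under that correction too, with a median of -1.14. The correlation estimated between the 15 genes was 0.607, far above the preset 0.01. In zone 3 of the PaNox1 mutant, 6 were lower and 9 did not pass, with a median of -0.62 (camera adjusted p = 0.00168; adjusted p = 0.999 with an estimated correlation), and 11 were lower with the second background correction. In zone 3 of ∆PaMpk1 also 6 were lower and 9 did not pass, with a median of -0.55 (camera adjusted p = 0.083), which was 0.17 with log2 ratios scaled to equal spread between arrays and -0.095 without the 6 compressed arrays, and the adjusted p was 0.0379 with Cy3 alone. In zones 1 and 2 of ∆PaMpk2, 4 and 3 were lower, with medians of -0.25 and -0.31 and camera adjusted p of 0.083 and 0.191, which became 5 and 6 lower with adjusted p of 0.0313 and 0.0336 with the second background correction (adjusted p = 0.86 for both with an estimated correlation). Between zones 1 and 3 of the wild type, 4 were lower in zone 3, 7 with the second background correction, with a median of -0.38 (camera adjusted p = 0.0137; adjusted p = 0.431 with an estimated correlation), which was -0.78 with processed signals, -0.71 with scaling between arrays and -0.77 without the 6 compressed arrays. Between zones 2 and 3 none of the 15 passed, and the camera adjusted p of 0.0216 for a median of 0.28 was 0.0676 with the second background correction and 0.431 with an estimated correlation. In zones 1 and 2 of ∆PaMpk1, 3 were lower and 1 higher each time, and in those of the PaNox1 mutant 0 were lower and 0 and 1 higher, with camera adjusted p of 0.507 to 0.996 in the 4 comparisons. Adjusted over the list alone, 10, 12 and 9 genes passed for zone 2 against zone 1 of the wild type and for zone 3 of ∆PaMpk2 and of the PaNox1 mutant. The medians of these 3 comparisons stayed negative under all 7 scalings, but with log2 ratios scaled to equal spread between arrays the lists of these mutants had medians of -0.29 and -0.30 and an adjusted p of 0.103. Without the 6 compressed arrays the median in the PaNox1 mutant was -0.37 (adjusted p = 0.0388).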

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

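The tests on the 6 compressed arrays, on the columns of the deposited table and on the zone score were chosen only after the results were seen; the counts over other splits of the arrays were planned, but not the keeping together of cultures in them.

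On 6 arrays log2 ratios were compressed, with slopes of 0.511 to 0.660 on their groups. Against RNA that differed in these samples and against poor array quality as the cause, 0 of the 6 arrays had a slope under those of the other 42 with no background subtraction, and 0 of the 6 with the scanner software's processed signals, although 2 of the 6 lay outside the range of the others in at least 1 of 5 quality measures. With spots of bright local background left out of the parameter fit, 6 of 6 arrays had slopes within the range of the others, which is consistent with these spots as the cause. The share of the variance within groups on its first axis fell from 33.3% to 16.4%.

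In the deposited table, 9 columns equalled the scanner file of another replicate of the same group, a signal in a table that was used here only as an alternative. If these columns were exchanged in the table, arrays of 1 strain and number should deviate together across zones under the scanner files' numbering, and they did so more than under the table's numbering, in 3 of the 3 strains (mean correlation 0.409 against 0.0196). Exchanged columns in the value table are therefore a candidate explanation, and such an exchange leaves groups and counts unchanged since no column left its group. No biological explanation was tested.

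Mutants scored lower than the wild type along the wild-type zone change in zones 2 and 3. If log2 ratios were narrower on the mutants' arrays, their spread should be lower than in the wild type. In 6 of 6 comparisons the mutants' ratios were as wide or wider with the second background correction, under which the same 6 score differences passed. With the planned correction the ratios were as wide or wider in 5 of 6. In zone 2 of ∆PaMpk2 the interquartile range was then 0.613 against 0.672 in the wild type. The reference is a pool of wild-type cultures, so mutant ratios may be wider for that reason. The spread over all genes therefore cannot decide on this explanation. A delay as the whole of the difference is argued against, for a part of the genes. At least 29.3% of the genes changed at least 2-fold in zone 3 of each mutant lay at least 2-fold beyond all 3 wild-type zone means. With the second background correction it was at least 33.6%. The choice of these genes already puts them 2-fold from the wild-type zone 3 mean, and the share that noise alone would give was not computed. A delay as a part of the difference may remain. Of the same genes, 36.9%, 37.6% and 44.1% in ∆PaMpk1, ∆PaMpk2 and the PaNox1 mutant had changed against the wild-type step from zone 1 to zone 2. Along that step 11.3%, 9.57% and 14.6% had changed. Of all genes, 20.2%, 21.4% and 19% lay against it. Other effects of the mutations may remain too, which the design cannot separate. The choice of the score genes on the wild type alone may account for a part as well, which was not tested.

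A single array lay far from the other 3 of its group in 7 of the groups checked, where chance, about 1 group in 20, gives 6.15. The wild-type zone score of wild-type zone 2 replicate 4 was -0.22, against 0.69 to 0.82, and 0.47, against 0.84 to 0.89, with the second background correction. Wild-type zone 3 replicate 2 had 8750 genes well above background in Cy3, against 9498 to 9632. The log2 ratio of Pa_2_2310 was -4.09 in wild-type zone 1 replicate 2, against -2.23 to -2.17. Pa_5_4670 was at 0.16 in wild-type zone 3 replicate 4, against 1.61 to 1.72. Pa_6_10630 was at -1.11 in ∆PaMpk1 zone 2 replicate 1, against -2.07 to -1.93. Pa_1_6440 was at -1.32 in wild-type zone 1 replicate 4, against -2.24 to -2.09. The arrays of these values of Pa_6_10630 and Pa_1_6440 had slopes that rose with the second background correction. Pa_5_11050 was at 1.79 in wild-type zone 3 replicate 4, against 0.26 to 0.31.

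The change across zones differed between mutant and wild type, by the F test of the difference itself, for 1146 genes in ∆PaMpk1, 1793 in ∆PaMpk2 and 1869 in the PaNox1 mutant. The reference channel carried signal of the mating-type genes FMR1, SMR1 and SMR2, which belong to the mat- type. They were well above background in Cy5 on 48, 46 and 45 of the 48 arrays and on 0 arrays in Cy3, where all strains are mat+ per the labels.

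For zone 2 against zone 1 and zone 3 against zone 2 of the wild type, where replicate numbers pair the samples, 8 splits of the arrays part all 4 pairs, too few for a share under 0.05. The real and the highest other counts among these 8 were 3268 and 523, and 639 and 2; splits that keep pairs together reached 2834 and 399. For the other 16 results the real split gave the highest count each time, a share under 0.05. It was 1 of 35 splits for pairwise comparisons. For zone changes it was also 1 of 35, with the arrays of a culture kept together over the zones. There, ∆PaMpk1 zone 1 replicate 4, of unmatched number, went with the culture that lacked a zone 1 array. For the mutants against each other it was 1 of 100 drawn, and 1 of 35 with cultures kept together. These shares are the smallest the splits can give, so they argue against chance without excluding it. If replicate numbers pair zone 3 with zone 1 of the wild type too, only 8 splits part all 4 pairs, again too few. Among these 8 the highest other count was 978. The real and the highest other counts were 4196 and 2050 for zone 3 against zone 1 of the wild type. In zones 1, 2 and 3 they were 3890 and 1403, 4064 and 1405, and 4463 and 1947 for ∆PaMpk1. They were 3783 and 2112, 4548 and 3095, and 4766 and 1126 for ∆PaMpk2, and 3094 and 1945, 3769 and 1386, and 2699 and 2267 for the PaNox1 mutant. For the zone changes they were 1146 and 89 in ∆PaMpk1, 1793 and 127 in ∆PaMpk2, and 1869 and 1328 in the PaNox1 mutant. For the mutants against each other they were 5542 and 3210 (∆PaMpk1 and ∆PaMpk2), 4710 and 3244 (∆PaMpk1 and the PaNox1 mutant), and 5260 and 2821 (∆PaMpk2 and the PaNox1 mutant).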

How the results depend on the processing

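The second background correction, scaling between arrays, slide as a fixed block, the culture block for zone steps within the mutants and leaving out 4 or 6 arrays were chosen after the data were seen; the other alternatives were planned. Numbers are counts of genes past the threshold. Counts stayed within 1.5 times the planned value for all 18 results with Aquantile, no filter, trend and robust options, the random slide block, both replicate blocks (ratios 1.01 to 1.21 fixed and 0.947 to 1.43 random), and for the 15 strain results with slide as a fixed block; Aquantile leaves log2 ratios as they are and is no test. Neither replicate block moved any of these 18 counts by that measure. Both blocks spanned all strains, and no separate paired fit of the wild-type zones was run. For these 18 results the culture block was run under the planned correction only, where its consensus correlation was 0.115 against 0.3 under the second. For zone 3 against zone 2 within ∆PaMpk1 the culture block gave 374 in place of 170.

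For zone 3 against zone 2 of the wild type (639), zone 3 of the PaNox1 mutant (2699) and the zone changes of ∆PaMpk1, ∆PaMpk2 and the PaNox1 mutant (1146, 1793 and 1869), counts were 1449, 4388, 2409, 2982 and 3360 with no background subtraction, 1581, 4592, 2101, 2770 and 3356 with processed signals, 1768, 4416, 2229, 2837 and 3347 with Cy3 alone, 1565, 4585, 2099, 2772 and 3352 with the deposited table, and 1445, 4329, 2356, 2879 and 3312 with the second background correction. The 6 compressed arrays had ordinary slopes with no subtraction, processed signals and the second correction; for Cy3 alone the cause was not tested. With arrayWeights, zone 2 against 1 and zone 3 against 2 of the wild type gave 6168 and 3506, ∆PaMpk1 in zones 1 and 2 6702 and 6396, ∆PaMpk2 in zone 1 6945, the PaNox1 mutant in zones 1 and 3 5489 and 4404, the 3 zone changes 6463, 6261 and 4798, and ∆PaMpk1 against ∆PaMpk2 and the PaNox1 mutant 8609 and 7664; limma warned that the estimation of these weights stopped before reaching its convergence tolerance, and the cause was not tested. Scaling between arrays gave 1411 for zone 3 against zone 2 of the wild type, 2611 for ∆PaMpk1 and 2413 for the PaNox1 mutant in zone 2; the cause was not tested. With fewer arrays in the model, the compared groups alone gave 217 for zone 3 against zone 2, 2105 for ∆PaMpk2 in zone 1, and 1997 and 1611 for the PaNox1 mutant in zones 1 and 3. Leaving out 4 arrays gave 1486 for zone 3 against zone 2 and leaving out 6, of which 2 are of wild-type zone 3, gave 111. Exchanging the zones of the 2 PaNox1 mutant arrays of conflicting titles gave 786 for its zone change, but the exchange is argued against: both arrays correlated best with their own groups, and with the second correction the wild-type zone score was -1.81 for the array described as zone 1 (others -1.91 to -1.67) and 0.30 for that described as zone 3 (others 0.48 to 0.80). Leaving both out kept all 6 counts of that mutant within 1.5 times (ratios 0.837 to 1.15).

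Leaving out 1 array in turn gave 2412 to 3617 for zone 2 against zone 1, 3265 to 4207 for zone 3 against zone 1, and 179 to 905 for zone 3 against zone 2, where 4 arrays moved the count by over 1.5 times: 298 and 377 without zone 2 replicates 2 and 3, and 295 and 179 without zone 3 replicates 2 and 3. Ranges in zones 1, 2 and 3 were 3298 to 3676, 3451 to 3877 and 3727 to 4645 for ∆PaMpk1, 3136 to 4083, 3866 to 4646 and 4261 to 4708 for ∆PaMpk2, and 2257 to 3533, 3254 to 3758 and 2198 to 3057 for the PaNox1 mutant. Zone changes ranged from 768 to 1314, 1359 to 2184 and 1485 to 2133, and mutants against each other from 5226 to 5566, 4374 to 4799 and 4824 to 5685.

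The share of higher genes in zone 2 against 1, 3 against 2 and 3 against 1 of the wild type was 56.0%, 65.6% and 58.8%, and 43.7%, 51.1% and 41.96% with processed signals, 43.9%, 50.5% and 41.1% with Cy3 alone, and 43.7%, 51.0% and 42.04% with the deposited table; the compared groups alone gave 52.5% for zone 3 against 2. The median of all genes shifted by over 0.1 only with processed signals and the deposited table, to -0.11 for zone 3 against 1 of the wild type and 0.11 and 0.10 for ∆PaMpk2 in zone 3. Of the values of named genes, 1211 kept direction and side of the threshold and 1 lost significance. These genes were named for the largest differences past the threshold in the same data, so this count is a weak test. It also includes the values under Aquantile. The mitochondrial median for zone 3 against zone 2 of the wild type, 0.28 without a call for any member, was -0.17 with scaling between arrays and -0.054 without the 6 arrays. Among comparisons in which the list did not pass as planned, the medians in zones 1 and 3 of ∆PaMpk1, -0.23 and -0.55, were 0.11 and 0.17 with scaling between arrays, and that in zone 2 of the PaNox1 mutant ran from -0.036 to 0.11. On the dimmest array 82.9% of the genes lay well above background in Cy3, which limits what low levels can show.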

Other observations

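The test of zone steps within the mutants, with its block, was chosen after the data were seen. Within ∆PaMpk1, 2118 genes differed between zones 2 and 1, 170 between zones 3 and 2 and 3701 between zones 3 and 1. Within ∆PaMpk2 the counts were 823, 1028 and 3169, and within the PaNox1 mutant 2440, 2244 and 4642. With the second background correction they were 2886, 610 and 4459, then 2279, 1586 and 4197, then 3840, 3402 and 5959. With strain and culture number as a random block they were 2487, 374 and 4027, then 1116, 1319 and 3520, then 2810, 2604 and 4936 under the planned correction, and 3854, 1573 and 5228, then 3423, 2533 and 5023, then 4851, 4378 and 6664 under the second. Each zone has its own slides and scan day here too.

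The 903 genes at least 2-fold higher in zone 3 than in zone 1 of the wild type had a median log2 change of 1.48 there, and of 0.80 in ∆PaMpk1, 0.42 in ∆PaMpk2 and 0.95 in the PaNox1 mutant. The sign of the wild type was kept by 822, 634 and 839 of them. With the second background correction the genes numbered 987, with medians of 0.77, 0.59 and 1.07 in the 3 mutants, and 868, 841 and 912 kept the sign. The 190 genes at least 2-fold lower had a median of -1.36 in the wild type, -0.48 in ∆PaMpk1, -0.71 in ∆PaMpk2 and -1.01 in the PaNox1 mutant. The genes were chosen on the wild type, so a smaller change elsewhere is expected in part from the choice itself.

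Genes changed in opposite directions in different zones of the same mutant numbered 130 of 6365 genes changed in any zone of ∆PaMpk1, 156 of 6904 in ∆PaMpk2 and 203 of 5661 in the PaNox1 mutant, and 232 of 7311, 358 of 7728 and 438 of 7212 with the second background correction. At least 2-fold in the same direction in all 3 zones were 160 genes higher and 394 lower in ∆PaMpk1, 282 and 289 in ∆PaMpk2, and 72 and 204 in the PaNox1 mutant. With the second background correction they were 167 and 411, 320 and 409, and 95 and 281.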
